A study of Anas platyrhynchos with 2 samples.

How the data were processed

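Small RNA of the duodenum was sequenced in a library of control ducks and a library of transported ducks, 1 per group. Per the labels' protocols, total RNA was extracted with Trizol, fragments of 20 to 30 nt were isolated from 10 µg of it on a 15% TBE-urea gel, and libraries followed standard Illumina protocols. Selection by size keeps miRNAs together with other fragments of that length. The aligner, the predictor of new miRNAs, the miRNA database release and the genome build are not given in the sources used here.

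The authors deposited a table with a row for each of 288 mature miRNAs, of which 246 carry chicken names and 42 are predicted miRNAs named novel_ and a number, with a scaffold position and a folding energy. Per the file headers, each library has a column of read counts and a column of TPM. The deposited TPM values equal the count divided by the library's sum over the table, scaled so that each library sums to 1e6, within 4.3e-05. They hold no term for length and are called CPM (counts per 1e6 counts) in the text. Whether reads were assigned to chicken or duck sequences is not stated, and a duck miRNA that differs from its chicken counterpart can lose counts by such a step. No comparison by the authors is in the table. Predicted rows were compared with sequences of miR-143-3p, miR-145-5p, miR-363-3p, miR-129-5p and miR-96-5p written down from general knowledge, with no database at hand.

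The library columns are named CC and CT. They were matched to the control and the transported sample by the last letter, since CC holds no letter T and the names differ only there. No label spells the names out, and CT can also abbreviate control, so the match is a reading and every direction is given as CT against CC.

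The depth was 5772509 counts in CC and 5272666 in CT, a ratio of 1.09. CPM was computed from these totals. The ratio of CT to CC is given with the exact conditional (Clopper-Pearson) 95% interval, and shares with the exact binomial interval. Reads carried no molecular identifiers that the sources mention, so intervals and floors cover counting error only. Where a library had 0 counts the ratio was taken against a floor of 3 counts and given as a bound. The rule of size was a ratio of at least 2 among miRNAs with at least 50 counts over both libraries, and 139 rows fell under that minimum. No test between the groups was possible with 1 library each.

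Lists of miRNAs for cell types and processes were fixed before the data were examined: intestinal epithelial, miR-200 family, endocrine and sensory epithelial, muscle, red blood cell, white blood cell, endothelial, pancreas and liver, neural, inflammation, hypoxia and p53, miR-17 and miR-92 clusters, let-7, miR-29 and miR-30, and HOX-linked with the miR-99, miR-100 and miR-125 families. A member was matched by name, and its more abundant arm stood for it. The median log2 ratio of each list with at least 3 members was placed among 10000 random lists. In these, each member was exchanged for a draw from the 20 miRNAs nearest to it in mean expression, itself and other members included. For the most abundant miRNAs these 20 reach far lower levels, so the match is loose there. miR-155 is in both the inflammation and the white blood cell list and had 1 count in each library. The named miRNAs are the 10 with the highest mean CPM, the 12 with the largest and the 12 with the smallest ratio among those with at least 50 counts (predicted miRNAs only from 1000 counts), members of the lists, and miR-2954.

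Ratios were recomputed with TMM factors (edgeR 4.0.16), median-of-ratios size factors (DESeq2 1.42.0), totals without the 10 most abundant miRNAs, other count minimums, a pseudocount of 5 CPM and a 1.5-fold rule. TMM shifted all log2 ratios by -0.05 and the size factors by -0.06. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, figures matplotlib 3.10.9, and R 4.3.3. The intervals and the 2-fold rule were tested on 100 simulated pairs of libraries with the depths and mean abundances of CC and CT, over 149 miRNAs of which 40 were changed. The intervals held the true ratio for 95.5% of miRNAs, and 100% of 4-fold changes passed the rule, against 0.60% of 1.5-fold changes and 0.064% of unchanged miRNAs. The simulated counts held Poisson (counting) error only, the error that the intervals assume, so these rates are not error rates for the conditions. Spread between animals and duplicated reads were not simulated.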

Results

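Small RNA was sequenced from the duodenum of female Jingjiang ducks, an egg-laying breed of domestic duck, at 1 day of age. In the study, 20 ducks were divided between a group carried for 8 h in a vehicle at 40 to 70 km per h and a control group that was boxed but not transported. Each group is represented by 1 library, and how many ducks went into a library is not given in the sources used here. The table names its libraries CC and CT. CC was read as the control library and CT as the transported library from the last letters of the names, which no label spells out. If that reading is wrong, every direction relative to transport reverses, so the libraries are called CC and CT below. The table held 5772509 counts for CC and 5272666 for CT over 288 mature miRNAs. With 1 library per group, no difference has a replicate check and no p-value is given. The 95% intervals are exact and cover counting error only, so they compare these libraries and not the conditions.

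The duodenal profile was led in both libraries by miR-215-5p, of the miR-192 and miR-215 family that is abundant in intestinal epithelium. It took 40.6% of the CC counts (exact interval 40.5 to 40.6%) and 43.5% of the CT counts (43.5 to 43.6%). The row named novel_1, whose sequence was recognised as that of miR-143-3p without a database, a miRNA abundant in smooth muscle and fibroblasts, took 16.4% in CC and 11.0% in CT. miR-148a-3p took 11.4% and 13.6%, miR-21-5p took 7.66% and 6.63%, and miR-194, another miRNA of intestinal epithelium, took 3.32% and 5.01%, each in CC and CT in that order. Levels below are in CPM, the count scaled to a common library total. The other members of the 10 most abundant were let-7f-5p, miR-146b-5p, let-7i, miR-7 and miR-200b-3p, with 6728 to 15584 CPM in CC and 9810 to 13696 CPM in CT.

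These shares made the profiles alike in overall shape. The 10 most abundant miRNAs of each library held 85.4% of the CC counts (85.3 to 85.4%) and 85.6% of the CT counts (85.5 to 85.6%), and 7 miRNAs were among the 10 in both. In CC 270 miRNAs had at least 1 count and in CT 271, with 253 in both, and with a minimum of 10 counts the numbers were 178 and 178. The 17 miRNAs seen only in CC had at most 9 counts. Of the 18 seen only in CT, miR-216c had 116 counts and the others at most 9. A count of 0 allows up to 0.520 CPM in CC and 0.569 CPM in CT. Across all listed miRNAs, which are not independent replicates, log2(CPM + 1) of the libraries had a Pearson correlation of 0.984 and a Spearman correlation of 0.949. miR-2954, an avian miRNA more abundant in males, had 436 CPM in CC and 437 CPM in CT, which does not check the sex of the ducks, since there is no male library to set it against.

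CT was compared with CC as single libraries, so differences cannot be assigned to transport or to the duodenal damage named in the labels. The widest differences lay in miRNAs of the pancreas. miR-217-5p, abundant in pancreatic acinar cells, was 53.1-fold higher in CT (interval 46.4 to 61.0), at 37.6 CPM in CC and 1996 CPM in CT. Its neighbours at the same locus in vertebrates went the same way. miR-216b was 30.0-fold higher (24.5 to 37.1), with 96 counts in CC and 2629 in CT. miR-216a was 74.4-fold higher (25.1 to 364), with 3 counts in CC and 204 in CT. miR-216c, with 0 counts in CC and 116 in CT, was at least 42.3-fold higher against a floor of 3 counts in CC. The lower limit of its exact interval, which also covers counting error in CT, was 33.9-fold.

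Among the 149 miRNAs with at least 50 counts over both libraries, 11 were at least 2-fold apart, 9 higher and 2 lower in CT. Besides the miRNAs of the pancreas, the higher ones were miR-193a-5p (2.91-fold, 1.92 to 4.51), miR-135a-5p (2.81-fold, 1.90 to 4.23), miR-375 (2.79-fold, 2.71 to 2.87), miR-365-3p (2.76-fold, 2.20 to 3.48) and miR-153-3p (2.43-fold, 1.58 to 3.81). Of these, miR-375, a miRNA of pancreatic islets and gut endocrine cells, was the most abundant, with 1206 CPM in CC and 3365 CPM in CT. The lower ones were miR-184-3p, at 123 counts in CC and 35 in CT (3.21-fold lower, 2.19 to 4.82), and novel_67 (2.15-fold lower, 1.62 to 2.88), which lay outside the naming rule and was chosen after its values were seen. The remaining 138 miRNAs were less than 2-fold apart, although 102 of the 149 had intervals that excluded a ratio of 1. Over the 149, the median log2 ratio of CT to CC was 0.02 (interquartile range -0.25 to 0.36), with 79 higher and 70 lower in CT, or 69 and 80 with TMM scaling. The number at least 2-fold apart was 3 with a minimum of 500 counts, and 46 when the minimum was replaced by at least 1 count in each library, which also leaves out miR-216c. miR-365-3p is the reverse complement over 19 nt of miR-365b-5p, which had 14 and 35 counts, and reads of such a pair can be hard to assign.

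**Figure D1:**
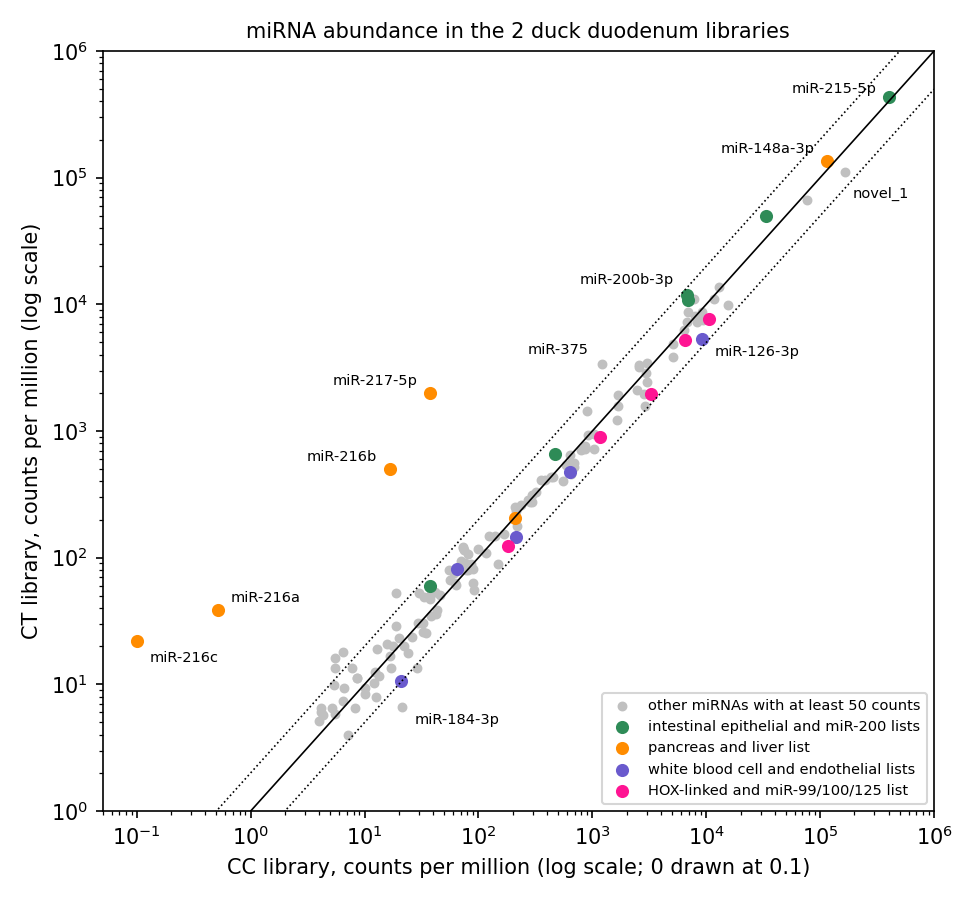
Abundance of the 149 miRNAs with at least 50 counts in the CC library (x axis, CPM, log scale, 0 drawn at 0.1) and in the CT library (y axis, CPM, log scale). Each point is 1 miRNA. Members of the intestinal epithelial, miR-200, pancreas and liver, white blood cell, endothelial and HOX-linked lists are coloured, and all others are grey. The solid line marks equal abundance and the dotted lines mark a 2-fold difference. miR-216a, miR-216b, miR-216c and miR-217-5p lie far above the band that holds most of the others, at ratios from 30.0 to 74.4. Within this range the ratio of miR-216c is a bound, not its drawn position.

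The list of pancreas and liver miRNAs, fixed before the data were examined, had 6 of 6 members with at least 50 counts. In CT, 5 were higher and 1 lower, and 4 of the 5 passed 2-fold. Its median log2 ratio was 5.15 with miR-216c at its bound, above all 10000 random lists of equal size matched on mean expression (percentile 100). The median was 2.58 with a minimum of 500 counts and 2.71 with a pseudocount of 5 CPM, both of which weigh on the miRNAs of low count. The members outside the miR-216 and miR-217 locus differed far less. miR-148a-3p, found in pancreas, liver and gut, was 1.19-fold higher (1.18 to 1.19), and miR-122-5p, specific to hepatocytes, was at 209 CPM in CC and 207 CPM in CT (log2 ratio -0.01, -0.13 to 0.11, and above 0 with totals that leave out the 10 most abundant miRNAs).

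Members of the miR-200 and intestinal epithelial lists were higher in CT, by less than 2-fold, and miR-375 of the endocrine and sensory epithelial list passed 2-fold. In the miR-200 family, which maintains the epithelial state, 3 of 3 members were higher. miR-200b-3p was 1.78-fold higher (1.75 to 1.80), miR-200a-3p 1.57-fold (log2 ratio 0.65, 0.63 to 0.67) and miR-429-3p 1.40-fold (log2 ratio 0.49, 0.41 to 0.56), and the median log2 ratio of 0.65 stood at percentile 99.8 of the random lists. These members come from a single cluster. Members of other lists also share clusters or transcripts, among them the pancreas, intestinal epithelial, white blood cell, HOX-linked and miR-17 and miR-92 lists. The random lists draw miRNAs independently, so the percentile of any list with such members can overstate how far it stands apart. The ratios are those of the more abundant arms, and the other arms differed, with miR-200a-5p lower in CT (log2 ratio -0.13, -0.20 to -0.05) and miR-200b-5p at 0.13 (-0.13 to 0.38). Of the intestinal epithelial list, 3 of 3 members were higher, with miR-31-5p at 1.59-fold, miR-194 at 1.51-fold and miR-215-5p at 1.07-fold, a median of 0.59 and a percentile of 95.3. In the endocrine and sensory epithelial list, miR-375 was 2.79-fold and miR-7 was 1.41-fold higher (1.39 to 1.43), while miR-183, with 37 and 39 counts, had an interval of the log2 ratio from -0.48 to 0.90. That list's median was 0.49, at percentile 88.6, and 0.99 with a minimum of 500 counts. These directions held with the other scalings tried.

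miRNAs of blood vessels, of white blood cells and of the list that joins HOX-linked miRNAs with the miR-99, miR-100 and miR-125 families were mostly lower in CT. The differences were less than 2-fold except for miR-223 with TMM scaling (log2 ratio -1.03) or size factors (-1.05). miR-126-3p, a miRNA of endothelial cells, was 1.72-fold lower (1.70 to 1.75), at 9134 CPM in CC and 5298 CPM in CT, whereas the less abundant arm miR-126-5p had a log2 ratio of -0.13 (-0.27 to 0.01). In the white blood cell list 3 of 4 members were lower, namely miR-223 of myeloid cells (1.97-fold, 1.43 to 2.76), miR-181b-5p (1.44-fold) and miR-181a-5p (1.33-fold), whereas miR-142-3p, found across blood cell lineages, was 1.26-fold higher (log2 ratio 0.33, 0.13 to 0.53). The list's median log2 ratio was -0.47, at percentile 1.51 of the random lists. In the list of HOX-linked miRNAs with miR-99a, miR-100 and miR-125b, 5 of 5 members were lower, with a median of -0.46 at percentile 1.09. Among them miR-99a-5p was 1.68-fold lower (1.64 to 1.72), miR-10b-5p 1.48-fold (1.34 to 1.63) and miR-10a-5p, the most abundant, 1.38-fold. Both neural miRNAs that matched the list by name with enough counts, miR-9-5p (1.38-fold) and miR-128-3p (1.35-fold), were lower as well. However, miR-219a, with 50 counts in CC and 59 in CT, did not match the list's miR-219 by name and was left out. The red blood cell miRNAs miR-451 and miR-144-3p had 10 and 9 counts in CC and 3 and 7 in CT, too few for a ratio here.

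Muscle miRNAs were divided. Of the 6 members with at least 50 counts 4 were lower and 2 higher in CT, or 5 and 1 with TMM scaling or median-of-ratios size factors, and the median of -0.14 stood at percentile 28.2. With totals that leave out the 10 most abundant miRNAs the median was -0.08. The intervals of 3 of the lower members excluded a ratio of 1, and those of both higher members did not. miR-1b-3p was 1.44-fold lower (log2 ratio -0.52, -0.56 to -0.49; its sequence is also contained in that of novel_27, with 3738 and 2943 counts) and miR-1a-3p 1.34-fold lower (-0.42, -0.45 to -0.39), while miR-133b had an interval of the log2 ratio from -0.01 to 0.83. novel_1, read as miR-143-3p, was 1.49-fold lower (log2 ratio -0.58, -0.58 to -0.57), whereas its neighbour novel_113, read as miR-145-5p, was close to equal (-0.04, -0.06 to -0.01). The predicted hairpin of novel_1 lies on the minus strand of scaffold KB742414.1 from 800752 to 800861, as the table gives it, with no build named and no annotation used here. The remaining miRNAs among the 12 with the smallest ratios were miR-218-5p (1.82-fold lower, 1.77 to 1.86), miR-490-5p (1.78-fold, 1.03 to 3.18), miR-214 (1.67-fold, 1.49 to 1.88), miR-455-5p (1.65-fold, 1.43 to 1.92), miR-146b-5p (1.59-fold, 1.57 to 1.61) and miR-21-3p (1.57-fold, 1.06 to 2.35).

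Among miRNAs induced in inflammation, 4 of 5 members with enough counts were lower in CT and 1 higher, with a median log2 ratio of -0.20 at percentile 13.4 that was -0.06 with all arms as members. Of the lower ones, 3 had intervals that excluded a ratio of 1, and that of miR-221-3p did not (log2 ratio -0.06, -0.14 to 0.02). The predicted row novel_168, close in sequence to miR-155 of this list and of the white blood cell list, was 1.26-fold higher (1.05 to 1.52). With it as a member, chosen after its values were seen, the median was -0.13 here and -0.41 in the white blood cell list. Besides miR-146b-5p, miR-21-5p was 1.16-fold lower (1.15 to 1.16) and miR-146c-5p 1.15-fold lower, while miR-146a-5p was 1.19-fold higher (log2 ratio 0.25, 0.03 to 0.47). miR-34a-5p, a target of p53 and the only member of the hypoxia and p53 list with at least 50 counts, was 1.47-fold higher (log2 ratio 0.55, 0.34 to 0.77). In the clusters of the miR-17 and miR-92 family, linked to cell proliferation, 9 of 9 members were higher, or 8 with TMM scaling, with a median of 0.22 at percentile 94.2. With median-of-ratios size factors miR-20a-5p was lower (log2 ratio -0.06), miR-17-5p was equal in the libraries, and the others were higher. The intervals of 5 members excluded a ratio of 1, and those of miR-17-5p, miR-18a-5p, miR-20a-5p and miR-20b-5p did not. The highest ratio was that of miR-18b-5p (1.73-fold, 1.17 to 2.57), and miR-92-3p was 1.26-fold higher. The row novel_163, read as miR-363-3p of these clusters and as abundant as miR-92-3p, was slightly lower (log2 ratio -0.04, -0.07 to -0.01), and with it as a member, chosen after its values were seen, the median was 0.18. The list as fixed had a median of 0.11 with a minimum of 500 counts. In the miR-29 and miR-30 list, 5 of 5 were higher, or 4 with TMM scaling or median-of-ratios size factors, with a median of 0.33 at percentile 91.3. It was led by miR-30e-5p at 1.61-fold (log2 ratio 0.69, 0.64 to 0.74). All 5 are miR-30 miRNAs, since miR-29a-3p, miR-29b-3p and miR-29c-3p fell under 50 counts. Of the let-7 family 5 of 7 were lower and 2 higher, or 4 and 3 with totals that leave out the 10 most abundant miRNAs, and the median of -0.10 stood at percentile 54.3. The let-7 median was -0.04 with those totals and -0.17 with median-of-ratios size factors. miR-32-5p was 1.75-fold higher (1.44 to 2.12).

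**Figure D2:**
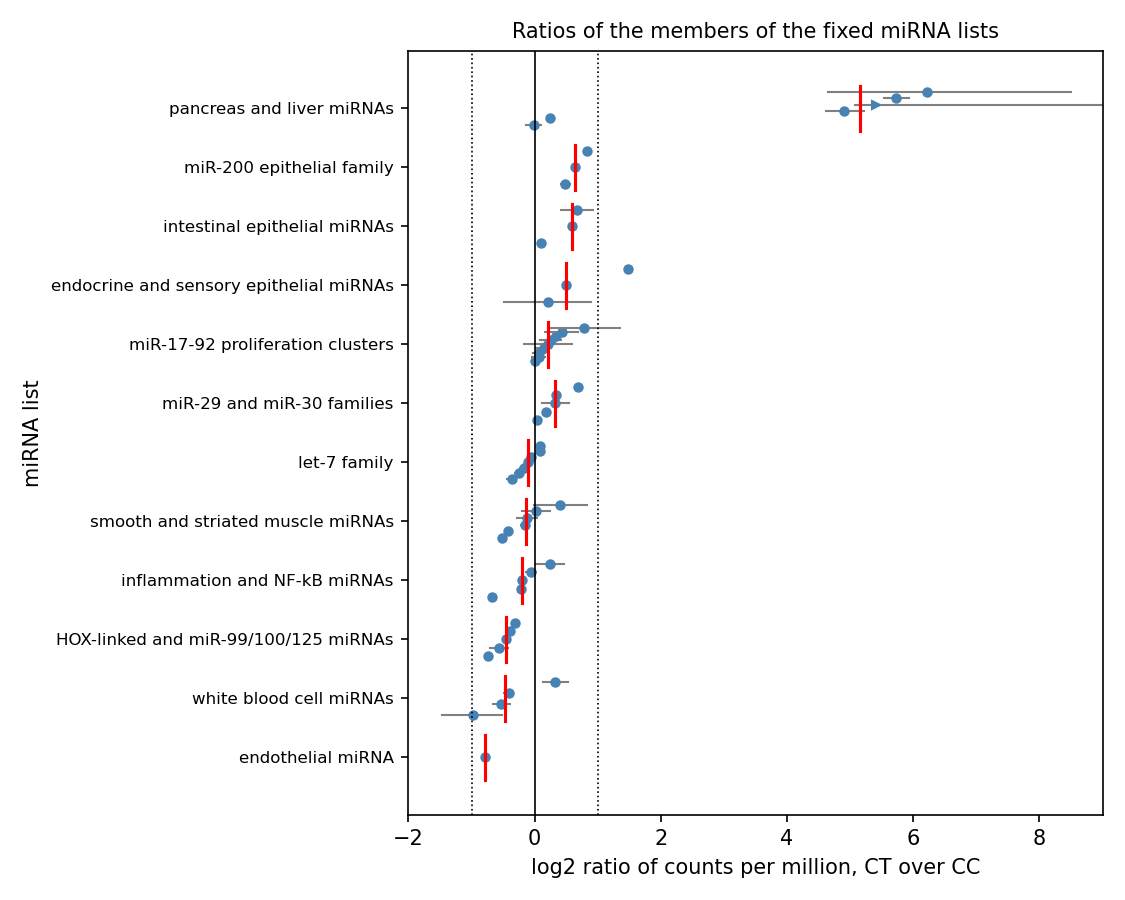
Log2 ratio of CPM, CT over CC (x axis), of each member with at least 50 counts of 12 miRNA lists (y axis). Points are miRNAs with their 95% exact counting intervals, the triangle is miR-216c at its bound with an interval open to the right, red bars are list medians and dotted lines mark a 2-fold difference. The pancreas and liver list has a median of 5.15, and the other medians lie between -0.79 and 0.65.

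In percentage points, the balance of the hairpin arms was close in both libraries for most hairpins. Where a single arm held nearly all counts, a difference in points is bound to be small. The difference was over 5 points in 6 hairpins and over 10 points in 3, whose intervals overlapped. The largest was 16.9 points for the miR-301b hairpin, with 31 counts in CC and 36 in CT. For 70 hairpins with both arms listed and at least 50 counts in all, the median absolute difference of the share of the 5p arm was 0.32 percentage points, and 9 hairpins had exact intervals that did not overlap. Each arm was taken under the single hairpin given for it. Some arms, such as miR-16-5p beside miR-16-2-3p, are not named for a single hairpin copy, so their shares may mix copies. The 5p arm of the miR-30e hairpin took 70.0% of its counts in CC (69.0 to 71.1%) and 77.8% in CT (77.0 to 78.6%). For the miR-200a hairpin the share was 7.87% in CC (7.62 to 8.13%) and 4.76% in CT (4.59 to 4.94%), and for the miR-126 hairpin it was 1.80% and 2.80%. In 2 hairpins the more abundant arm differed between the libraries, with intervals that overlapped in both cases.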

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

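Leaving out the miR-216 and miR-217 rows from the totals, leaving out the antisense partner rows, adding novel_1 and novel_113 to the muscle list adding novel_168 as miR-155 and adding novel_163 as miR-363 were chosen after seeing the data; the other settings were planned. The number of miRNAs at least 2-fold apart was 11 (9 higher and 2 lower in CT), and stayed within 1.5 times of each of these under TMM, size factors, totals without the 10 most abundant miRNAs and the settings chosen afterwards. It was 46 (29 higher, 17 lower) with no minimum and at least 1 count in each library, which also leaves out miR-216c, 3 (3 higher, 0 lower) with a minimum of 500 counts and 33 (22 higher, 11 lower) with the 1.5-fold rule. With a pseudocount of 5 CPM, 1 was lower. Detection with at least 10 counts gave 178 in CC and 178 in CT, and CC thinned to the depth of CT had 267 on average. The correlation over miRNAs with at least 50 counts was 0.969. The median of the miR-200 list was 0.60 with TMM, 0.58 with size factors, 0.71 without the 10 most abundant and 0.49 with all arms. That of the HOX-linked list was -0.50, -0.52, -0.40 and -0.39 under these settings in turn, and -0.42 with no minimum. The white blood cell list had -0.37 with all arms. The pancreas and liver list had 4.91 with no minimum, which leaves out miR-216c at 0 counts, 2.58 with a minimum of 500, which leaves out miR-216a and miR-216c, and 2.71 with the pseudocount. For the other movements the cause was not tested. The medians of the 7 other lists kept their sign in 52 values, but some moved by over 1.5 times: endocrine to 0.99 and miR-17 and miR-92 clusters to 0.11 with a minimum of 500, inflammation to -0.06 with all arms and to -0.13 with no minimum or with novel_168, let-7 to -0.04 and muscle to -0.08 without the 10 most abundant, and let-7 to -0.17 with size factors. Of 296 values for 74 miRNAs, those named and all list members with at least 50 counts, 10 changed sign. With TMM and size factors these were miR-2954 (-0.04 and -0.06), miR-20a-5p (-0.04 and -0.06), miR-499-5p (-0.02 and -0.04) and miR-30d (-0.01 and -0.03), and without the 10 most abundant miR-122-5p (0.05) and let-7a-5p (0.0058). Count minimums do not alter the ratio of a single miRNA. No mature sequence is repeated in full in the table, which gives no library total other than its sum, so keeping repeats or using such a total gave no other value. No paired analysis was possible because each group has 1 library. Depth limits the ratios of the 139 miRNAs under 50 counts.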

Other observations

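The tests of pancreatic tissue, of scaling, of a response to transport and of the share of epithelium were chosen after the ratios were seen; those of GC content and length were set before their result was computed.

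The predicted rows held 17.6% of the counts in CC and 12.1% in CT, most of them in rows that were read as known miRNAs. In 5 of them the sequence equals that of a conserved vertebrate miRNA without a row under its own name, as written down from general knowledge and not checked against a database. These held 98.7% of the predicted counts in CC and 98.5% in CT. They are novel_1 with miR-143-3p, novel_113 with miR-145-5p, novel_163 with miR-363-3p, novel_40 with miR-129-5p and novel_151 with miR-96-5p. The hairpins of novel_1 and novel_113 lie 602 nt apart on scaffold KB742414.1, as the neighbouring miR-143 and miR-145 genes of other vertebrates do. A further 8 rows are within 3 edits of a named row and share its first 8 bases. One is novel_168, with 216 counts in CC and 249 in CT (1.26-fold higher in CT), beside the chicken-named miR-155 row with 1 count in each. Another is novel_67, close to miR-10a-5p, which was 2.15-fold lower in CT. These rows were chosen after their values were seen.

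miR-216a, miR-216b, miR-216c and miR-217-5p were far higher in CT. Scaling between the libraries is argued against, since it would shift all miRNAs alike, and the upper quartile of the log2 ratios of the other 145 miRNAs with at least 50 counts was 0.34, against a smallest lower limit of 4.61 among these. A candidate explanation is pancreatic tissue in the CT sample, the pancreas lying in the loop of the duodenum. miR-375, abundant in pancreas and encoded elsewhere, was higher too, with a ratio of 2.79, which was known when the explanation was raised and so does not test it, with miR-7 at 1.41 and miR-148a-3p at 1.19, though all 3 are also expressed in gut epithelium and miR-148a-3p was among the 3 most abundant miRNAs of both libraries. A response of the duodenum to transport stays open and cannot be told apart from it with 1 library per group; the counts of miR-217-5p to miR-216b stood at 2.26 in CC (1.77 to 2.91) and 4.0 in CT (3.83 to 4.18).

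In CT the 6 members of the intestinal epithelial and miR-200 lists were higher, and 9 of 10 members of the HOX-linked, white blood cell and endothelial lists were lower, all but miR-142-3p. The sets were formed after these directions were seen, so the difference of 1.11 between their medians on the log2 scale describes the pattern and does not test it. A linear bias by GC content as the whole cause is argued against by the small size of the linear trend over 145 miRNAs. Relative to the median GC content, the trend moved no miRNA by more than 0.23 on the log2 scale. Removing it left a difference of 1.09. The interval was 0.78 to 1.35 when members were resampled, those of clusters known in vertebrates and of their paralogous copies together. It rests on only 3 epithelial units and 7 others. The trend itself was weak (Pearson correlation -0.18), so its removal could change little, and neither the 1.09 nor its interval is further evidence. A GC bias of another form was not tested. For mature length the trend was close to absent (Pearson correlation 0.02), and both sets had a median of 22 nt. A linear bias by length is thus argued against as the cause, and removing the trend left 1.11. Selection by size in another form was not tested. A larger share of epithelium in the CT sample may account for the pattern, though the minor arms miR-200a-5p and miR-126-5p did not follow their partners, and an effect of transport was not tested apart from it. The epithelial members did not rise alike either, with log2 ratios from 0.10 for miR-215-5p, the most abundant, to 0.83 for miR-200b-3p. A change in share predicts that miRNAs of the muscle coat fall alike, but the log2 ratios of miR-145 and miR-143, if rightly read from novel_113 and novel_1, were 0.54 apart, and with no replicates there is no spread to set that against, so the explanations cannot be told apart.

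Of 4 pairs of rows that are reverse complements over at least 16 nt, 2 had counts within 1 of each other in both libraries. miR-458a-3p had 421 and 635 counts in CC and CT and miR-458b-5p had 420 and 634, and miR-219a and miR-219b both had 50 and 59. Some sequences are contained in that of another row. miR-29a-3p and miR-29c-3p both had 9 and 12 counts and novel_90 and novel_91 both had 5 and 8, while novel_27, with 3738 and 2943 counts, is nested with miR-1b-3p at 16277 and 10351. How reads were shared between such rows is not given in the sources used here.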
